A study of Mus musculus with 4 samples.

How the data were processed

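Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on mouse neural progenitor-like cells derived from embryonic stem cells of strain 129/SvJ, at passages 15 to 18 per the labels. Cells were fixed with 1% formaldehyde for 10 min and their chromatin was sonicated to fragments of 200 to 500 bp per the labels' protocols. Of the 4 libraries, 3 were precipitated with the M2 antibody against the FLAG tag and 1 with an antibody against histone H3 dimethylated at lysine 4 (H3K4me2), a mark of active or poised promoters and enhancers. Each group held 1 library, so no value has a replicate error and no test between conditions was possible.

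Samples were grouped by their titles. The titles of 2 FLAG libraries name Pax6 and Etv6. The title of the remaining FLAG library names N31, EGFP and the letters OK, and which protein carried the tag in it is not given in the sources used here. It is called EGFP_OK throughout. The series' design text speaks of 3 transcription factors, so it may hold a tagged factor other than Pax6 and Etv6. The title of the H3K4me2 library names N31, Oct4, EGFP and 0 hr. The Pax6 and Etv6 titles name NS in place of N31, and whether all libraries come from the same line of cells is not given in the sources used here.

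The submitters' processing notes name CASAVA 1.8.1, BWA 0.6.2 and MACS 1.4.2 and the genome build mm9, with no order or role given. Per the file headers, peaks were called by MACS 1.4.2 separately on each library, without a control file, with a p cutoff of 1e-05, an effective genome size of 1.87e+09, a band width of 300 bp, a model fold of 10 to 30, a regional background range of 10 kb and at most 1 tag kept per position. Tags were 75 bp long. With no control, each peak was judged against the background of the same library, so differences in chromatin accessibility, copy number or repeat content stay in the lists. Each file gives, per peak, its position, its summit and the count of tags, deposited by the authors without normalization. It also gives a score that is 10 times the −log10 of the peak caller's p-value, per the file headers, and the fold enrichment, which is the ratio of the summit to the local background, per the file headers. These scores and folds are the authors' own values and were used here only to describe, rank or filter peaks within a list. The highest score a peak can reach in these lists is 3100.

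Depth was taken from the file headers. The EGFP_OK library had 35255051 tags, of which 21498324 were kept after removal of duplicates. The Pax6 library had 27560633 tags and kept 5288154, the Etv6 library had 31059965 and kept 24071748, and the H3K4me2 library had 29371583 and kept 24550365. The headers give redundant rates of 39%, 81%, 22% and 16% in that order. A peak in the Pax6 list rested on a median of 19 tags, against 47 in the EGFP_OK list, 54 in the Etv6 list and 120 in the H3K4me2 list.

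Overlaps were computed from the lists with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, on chromosomes 1 to 19 and X. Peaks on chromosome Y and on unplaced sequences were left out of the comparisons (38 of EGFP_OK, 42 of Pax6, 53 of Etv6 and 111 of H3K4me2). FLAG lists were compared by overlap of at least 1 bp, and FLAG lists were compared with H3K4me2 by whether the summit lay inside an H3K4me2 peak. Each share was set against 1000 circular shifts of the second list along each chromosome, by at least 1 Mb, which keep the widths and the clustering of the peaks, and against 200 shifts for the alternatives. The shifts describe where these lists lie and do not measure replicate error. Intervals are exact (Clopper-Pearson) 95% binomial intervals. They cover counting error only, and neighbouring peaks are not independent of each other. On simulated lists of 16604 peaks with the widths of the Pax6 list and a planted overlap of 0%, 20% and 70% with the Etv6 list, the excess over the shifts recovered 0.140%, 20.3% and 69.7%. Each list was ranked by its score and also described in 10 equal parts by rank.

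The design, the alternatives and the rule for naming regions were fixed before the data were examined. The classes of FLAG peaks by partner, the distances between summits, the shares of H3K4me2 peaks with a FLAG summit, the shares per chromosome and the densest windows were added afterwards, as descriptions. The rule named the 5 highest-scoring peaks of each library and the 5 shared regions with the best worst rank in each comparison. Because nearly all of these were the same few places, further regions were chosen after their values were seen, by the same ranking among peaks found in 1 FLAG list only, in a given pair only, or in all 3 FLAG lists outside the top 20 of any library. The regions are given by position in mm9. The gene table at hand was of assembly GRCm38, a different build, so peaks were not assigned to genes, and the planned promoter shares, gene list counts, motif shares and tests of the factors' own loci were not run. Alternatives covered the overlap rule, the score threshold, list length, peak width, the random placement, the ranking measure and the peaks found in all 3 FLAG lists. Settings with a false discovery rate of 5% had also been fixed and were not run, because the lists carry no such column.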

Results

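Genome-wide occupancy was profiled by ChIP-seq in mouse neural progenitor-like cells grown from embryonic stem cells, in a study of transcription factors that interfere with dedifferentiation and induce direct conversion. The FLAG-tagged factors named by the sample titles were Pax6, a paired-box and homeobox transcription factor of the developing eye and forebrain, and Etv6, a transcription factor of the ETS family. The label of the remaining FLAG library, EGFP_OK, names no tagged factor, and 1 library profiled H3K4me2. There was 1 library per factor or mark and no control library, so each value below has counting error only and no replicate check.

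The H3K4me2 list held the most peaks and the Pax6 list the fewest. On chromosomes 1 to 19 and X, 49457 H3K4me2 peaks covered 94.998 Mb, 30931 Etv6 peaks covered 38.5 Mb, 28338 EGFP_OK peaks covered 35.0 Mb and 16604 Pax6 peaks covered 17.4 Mb. H3K4me2 peaks were also the widest, with a median of 1628 bp, against 1143 bp for EGFP_OK, 1113 bp for Etv6 and 971 bp for Pax6. Peaks wider than 3 kb made up 14.4% of the H3K4me2 list and 1.21% of the Etv6 list, 0.861% of the EGFP_OK list and 0.307% of the Pax6 list. Peaks held 34.3% of the kept tags of the H3K4me2 library and between 7.45% and 8.91% of those of the FLAG libraries. The authors' median fold enrichment was 10.6 in the Pax6 list, 7.04 in EGFP_OK, 6.26 in Etv6 and 5.82 in H3K4me2. The Pax6 library kept 5288154 tags after removal of duplicates, against 21498324 for EGFP_OK, 24071748 for Etv6 and 24550365 for H3K4me2, so list lengths and folds were not compared at equal depth.

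The peaks were spread unequally over the chromosomes, of which 3 are named here after their values were seen, and the Pax6 and Etv6 lists were spread more like each other than like the EGFP_OK list. Chromosome 3 held 9.72% of the EGFP_OK peaks (95% interval 9.38 to 10.1), against 7.25% (6.96 to 7.54) of Etv6 and 7.95% (7.54 to 8.37) of Pax6, with 7.04% of H3K4me2. Chromosome 14 held 4.41% of EGFP_OK peaks (4.17 to 4.65), against 2.51% (2.33 to 2.69) of Etv6 and 2.88% (2.64 to 3.15) of Pax6, with 3.96% of H3K4me2. Chromosome 9 went the other way, with 3.64% of EGFP_OK peaks (3.42 to 3.86), 5.59% (5.33 to 5.85) of Etv6 and 5.34% (5.00 to 5.70) of Pax6, and 4.92% of H3K4me2. The EGFP_OK and H3K4me2 titles name N31 and the Pax6 and Etv6 titles NS. A difference between the cells therefore cannot be told apart from one between the tagged proteins. The ratio of the EGFP_OK share to the Etv6 share ran from 0.651 on chromosome 9 to 1.76 on chromosome 14, while the ratio of the Pax6 share to the Etv6 share ran from 0.801 on chromosome 11 to 1.23 on chromosome X.

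**Figure D1:**
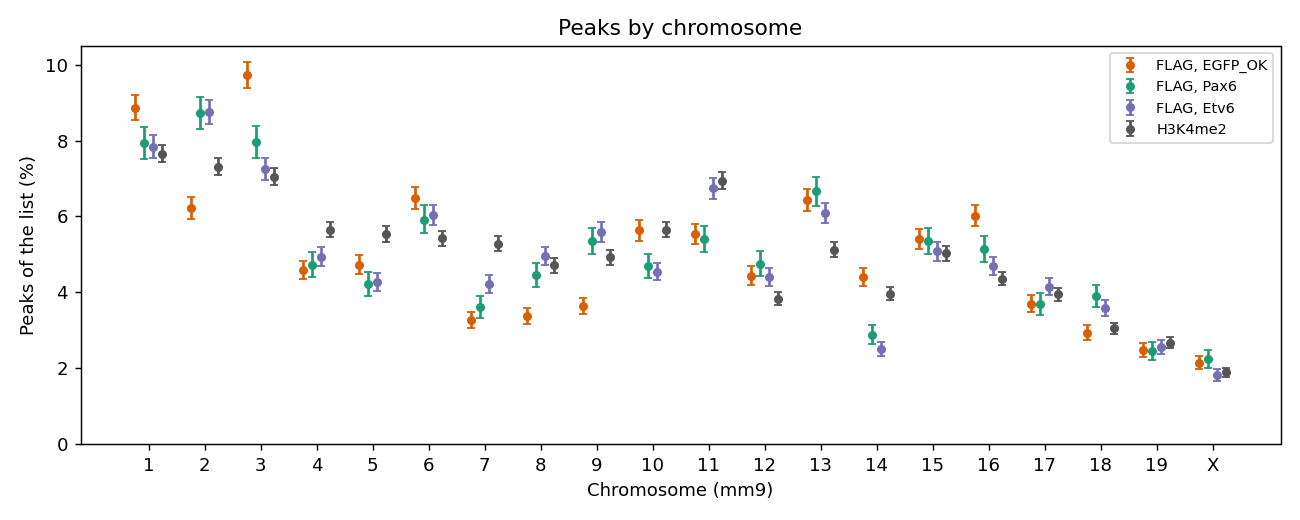
Share of each list's peaks (%, vertical axis, from 0) on each chromosome of mm9 (horizontal axis), 1 library per colour, with exact 95% binomial intervals as bars. EGFP_OK lies above Pax6 and Etv6 on chromosomes 3 and 14 and below them on chromosome 9.

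To ask whether the same places were occupied, the FLAG lists were compared with each other. Pax6 and Etv6 peaks coincided at most Pax6 sites, and EGFP_OK peaks lay mostly elsewhere. An Etv6 peak overlapped 12050 of the 16604 Pax6 peaks, which is 72.6% (95% interval 71.9 to 73.3), against a mean of 2.96% and at most 3.46% under circular shifts. An EGFP_OK peak overlapped 20.1% of the Pax6 peaks (19.5 to 20.7), against at most 3.11% under shifts. Of the 28338 EGFP_OK peaks, 20.9% (20.5 to 21.4) overlapped an Etv6 peak and 11.7% (11.4 to 12.1) a Pax6 peak, against at most 3.58% and 1.85% under shifts. Peaks of all 3 FLAG lists met at 2757 Pax6 peaks, or 16.6% (16.04 to 17.2), against at most 0.729% when the other 2 lists were shifted together. Peaks in no other FLAG list numbered 21815 for EGFP_OK (77.0%), 15739 for Etv6 (50.9%) and 3969 for Pax6 (23.9%). With only peaks of a score of at least 100 in both lists, the EGFP_OK share with Etv6 was 13.1%, but it was 21.2% (20.5 to 21.9) when only the EGFP_OK list was restricted, and with equal list lengths the Pax6 share with both others was 9.35%. The fold depended on the reference. Over the shifts it was 24.5 for Pax6 with Etv6, 6.57 for EGFP_OK with Etv6 and 7.41 for Pax6 with EGFP_OK. Against the lists' shares of the 83716 pooled regions of the 4 lists, the ratios were 2.00, 0.604 and 0.634 in that order. That pool holds only regions of the lists themselves, so unrelated lists would also fall below its expected value. The low ratios therefore do not show that EGFP_OK avoids the other factors' sites.

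The coincidence of Pax6 and Etv6 was higher among the higher-scoring peaks. An Etv6 peak was found at 96.9% (96.0 to 97.7) of the highest 10% of Pax6 peaks and at 52.0% (49.6 to 54.4) of the lowest. A Pax6 peak was found at 85.9% (84.7 to 87.1) of the highest 10% of Etv6 peaks and at 14.7% (13.4 to 15.97) of the lowest. Ranked by fold enrichment, the difference shrank for Pax6 peaks, to 82.7% in the highest 10% and 74.5% in the lowest, and for Etv6 peaks, to 68.6% and 23.7%. With the Pax6 list alone restricted to a score of at least 100, 323 of 4202 Pax6 peaks had no Etv6 peak, and at a score of at least 200 this held for 5 of 530. The median Etv6 peak with no Pax6 peak held 45 tags, against 75 tags for one with a Pax6 peak. Scaled by the ratio of kept tags, 0.220, the former would give about 9.89 tags in the Pax6 library, and scaled by the median ratio of matched peaks, 0.290, which counts only sites called in both lists, about 13.1. The weakest called Pax6 peak had 10 tags, so these values leave open whether Pax6 was absent or under the calling limit at such sites. For EGFP_OK peaks the share with an Etv6 peak was 24.5% (22.96 to 26.2) in the highest 10% and 18.8% (17.4 to 20.3) in the lowest. This small difference turned round when peaks were ranked by fold enrichment, with 19.7% in the highest 10% and 35.8% in the lowest. The other pairings with EGFP_OK were more frequent in the highest 10% by score than in the lowest, and were not ranked by fold enrichment. An EGFP_OK peak was found at 28.7% (27.1 to 30.3) of the highest 10% of Etv6 peaks and 11.8% (10.7 to 13.02) of the lowest, and at 30.5% (28.3 to 32.8) and 16.98% (15.2 to 18.9) of Pax6 peaks. A Pax6 peak was found at 18.4% (16.98 to 19.9) of the highest 10% of EGFP_OK peaks and 8.29% (7.30 to 9.37) of the lowest.

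**Figure D2:**
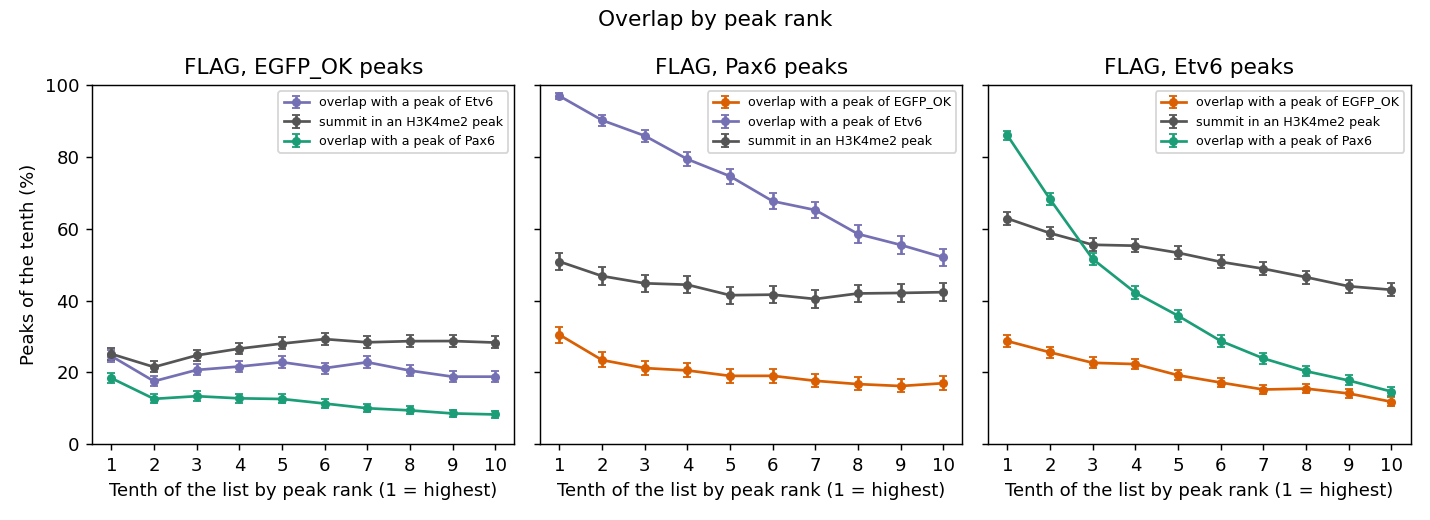
Share of the peaks (%, vertical axis) in each of 10 equal parts of a FLAG list, ordered by the authors' score (horizontal axis, 1 = highest), that overlap a peak of another FLAG list or have their summit in an H3K4me2 peak. Bars are exact 95% binomial intervals; the Pax6 and Etv6 overlap falls from 96.9% to 52.0% in the Pax6 panel, while all curves of the EGFP_OK panel stay under 30%.

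Where Pax6 and Etv6 peaks overlapped, their summits lay close together. The median distance was 76 bp over 12050 pairs, and 60.5% of the pairs (59.7 to 61.4) had summits within 100 bp. For EGFP_OK the median distance was 129 bp to Etv6 summits and 130 bp to Pax6 summits, with 42.8% (41.5 to 44.1) and 43.1% (41.4 to 44.8) within 100 bp. Across matched peaks, which are not independent replicates, Spearman's rho of the fold enrichments was 0.38 for Pax6 with Etv6, 0.26 for EGFP_OK with Etv6 and 0.29 for EGFP_OK with Pax6. For the scores it was 0.443, 0.127 and 0.164 in that order.

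To relate binding to active chromatin, FLAG summits were placed on the H3K4me2 peaks. Etv6 summits lay in H3K4me2 most often and EGFP_OK summits least often. Of the Etv6 summits, 51.9% (51.3 to 52.4) were inside an H3K4me2 peak, against 43.7% (42.9 to 44.4) of Pax6 and 26.9% (26.4 to 27.5) of EGFP_OK summits. Circular shifts gave at most 4.35%, 4.49% and 4.37%, so each list was placed on H3K4me2 more than its shifted copies. With 16604 top-ranked peaks from each list, the shares were 56.8% for Etv6, 43.7% for Pax6 and 25.8% for EGFP_OK. For Etv6 and Pax6 the trend with rank turned round between measures, and for EGFP_OK it kept its direction. The share in H3K4me2 was 62.8% in the highest 10% of Etv6 peaks by score and 43.0% in the lowest, but 54.7% and 58.2% by fold enrichment. For Pax6 it was 50.8% and 42.3% by score, but 38.9% and 53.8% by fold enrichment. For EGFP_OK it was 25.1% and 28.3% by score, and 18.5% and 47.6% by fold enrichment.

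The EGFP_OK peaks differed by their partners. Those found in no other FLAG list had 13.96% (13.5 to 14.4) of their summits in H3K4me2, whereas 74.4% (72.9 to 75.9) of those shared with Etv6 only and 72.1% (70.4 to 73.8) of those shared with both Pax6 and Etv6 did. The 591 shared with Pax6 only lay between, at 39.9% (35.96 to 44.01). Counted from the Pax6 list, 72.8% (71.1 to 74.5) of the sites in all 3 FLAG lists were in H3K4me2, and counted from the Etv6 list 72.6% (71.0 to 74.3). Pax6 and Etv6 sites without EGFP_OK were less often marked, with 44.3% (43.3 to 45.4) of the 9293 Pax6 summits in H3K4me2. The Etv6 peaks in no other list had 47.6% (46.9 to 48.4), and the Pax6 peaks in no other list had 22.2% (21.0 to 23.6). The latter were weak calls, with a median of 14 tags, against 15 to 24 in the other Pax6 classes. The lowest 10% of all Pax6 peaks by score, with a median of 12 tags, had 42.3%. Pax6 peaks with a summit outside H3K4me2 still had an Etv6 peak in 63.3% of cases (62.3 to 64.3), against at most 3.40% under shifts. Inside H3K4me2 the share was 84.5% (83.6 to 85.3).

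**Figure D3:**
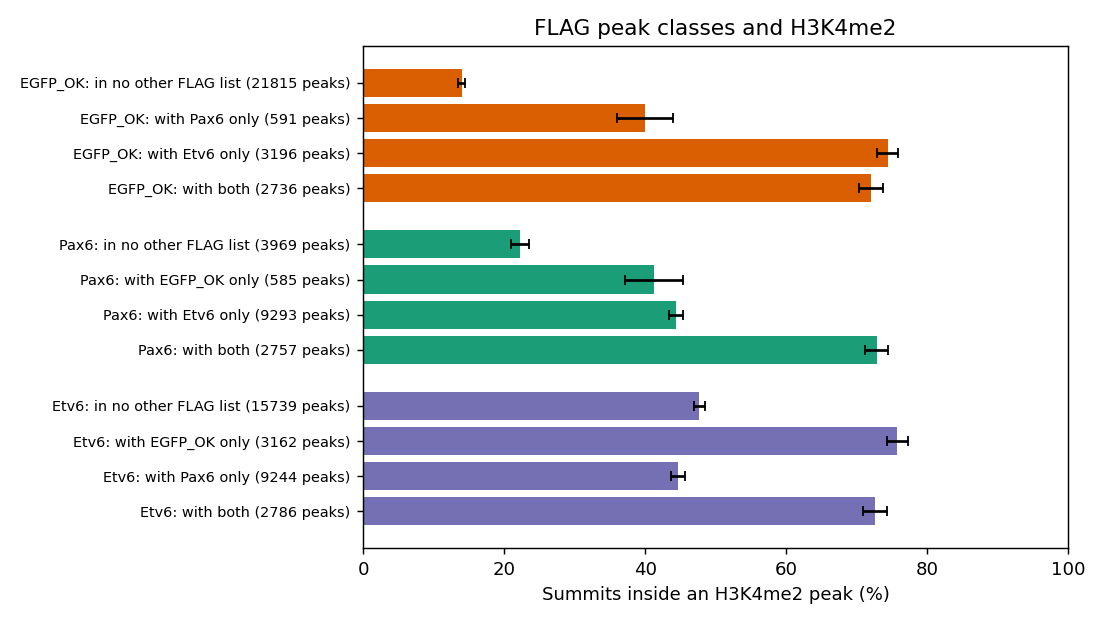
Share of summits inside an H3K4me2 peak (%, horizontal axis, from 0) for each class of FLAG peak, with the number of peaks in brackets and exact 95% binomial intervals as bars. EGFP_OK peaks in no other FLAG list are lowest at 13.96%, and peaks shared by EGFP_OK and Etv6 lie between 72.1% and 75.8%.

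Seen from the H3K4me2 list, 40.3% (39.9 to 40.8) of the 49457 peaks held a FLAG summit. Etv6 summits were in 31.9% (31.5 to 32.3), EGFP_OK summits in 15.3% (15.0 to 15.6), Pax6 summits in 14.5% (14.2 to 14.8) and summits of all 3 in 4.01% (3.84 to 4.19). In the highest 10% of H3K4me2 peaks 60.4% held a FLAG summit, and in the lowest 10% 22.8%. H3K4me2 peaks with a FLAG summit had a median width of 2133 bp, against 1384 bp for those without, and the shares were not adjusted for width. The median distance of FLAG summits from the H3K4me2 summit was 345 bp for Etv6, 371 bp for Pax6 and 367 bp for EGFP_OK. Positions drawn evenly within the same peaks lay farther away, at medians of 525, 548.5 and 548 bp. Within 100 bp of the H3K4me2 summit lay 13.1% (12.3 to 13.8) of the EGFP_OK summits against 9.94% of even positions. For Etv6 the values were 10.0% (9.58 to 10.5) and 10.4%, and for Pax6 9.13% (8.48 to 9.81) and 10.0%.

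The regions named by the fixed rule, which takes the first few ranks, were nearly the same in every list. A region on chromosome X (166527033 to 166527633 in the Etv6 list) ranked first in the EGFP_OK, Etv6 and H3K4me2 lists and at 3 in the Pax6 list. A region on chromosome 9 (35112351 to 35113519) ranked 2, 1, 2 and 2 in the EGFP_OK, Pax6, Etv6 and H3K4me2 lists. Regions on chromosome 2 (98505869 to 98507896), chromosome 12 (3109402 to 3110357) and chromosome 6 (103598670 to 103599623) were likewise among the top 12 of all lists. Their tag counts differed less between Pax6 and Etv6 than the depths did. The chromosome X region had 475 tags in EGFP_OK, 440 in Pax6, 433 in Etv6 and 392 in H3K4me2, although the Pax6 library had 0.220 times the kept tags of the Etv6 library. The remaining regions of the rule were chromosome 15 from 74915524 to 74918044 in the EGFP_OK list, shared with Etv6, chromosome 2 from 98502188 to 98503341 in the Pax6 list, and chromosome 1 from 24617896 to 24623505 in the EGFP_OK list, with 4613 tags at 3.63-fold.

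Further regions were chosen after their values were seen, to describe each class. Among peaks found only in the EGFP_OK list, the highest lay on chromosome 10 (90171429 to 90173094, 18.5-fold, 318 tags), outside H3K4me2, and the next on chromosome 14 (118628789 to 118630595, 15.4-fold, 387 tags), overlapping H3K4me2. Another on chromosome 10 reached 21.4-fold (88949433 to 88951050, 307 tags), outside H3K4me2. The highest Etv6-only peaks lay on chromosome 8 (73196472 to 73198357, 15.4-fold, 288 tags) and chromosome 13 (78622035 to 78623659, 11.7-fold, 296 tags), and both overlapped H3K4me2. The highest Pax6-only peak lay on chromosome 13 (102630234 to 102631205, 20.2-fold, 56 tags), outside H3K4me2. A pair of Pax6 peaks on chromosome 15 at 61004572 to 61006804 (8.72-fold) and 61060753 to 61062297 (11.1-fold) were also in no other FLAG list.

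Of the sites shared by Pax6 and Etv6 but not EGFP_OK, the best ranked lay on chromosome 10 (27132834 to 27134639 in the Pax6 list), at 11.1-fold in Pax6 and 7.92-fold in Etv6, overlapping H3K4me2. On chromosome 3 a site at 37992935 to 37994283 reached 17.5-fold in Pax6 and 15.4-fold in Etv6, and one at 38026875 to 38028213 reached 12.99-fold and 12.8-fold, both outside H3K4me2. Of the sites in all 3 FLAG lists outside the top 20 of any list, the best ranked lay on chromosome 12 (44073311 to 44074235 in the Pax6 list), outside H3K4me2. It reached 28.5-fold in Pax6, 29.1-fold in Etv6 and 24.4-fold in EGFP_OK. Its summits were at 44073943, 44073939 and 44073946. The next ranked, on chromosome 9 (51842732 to 51844594) and chromosome 2 (157738757 to 157739879), were also outside H3K4me2. The site on chromosome 3 at 95848260 to 95849402 reached 19.2-fold, 17.4-fold and 15.1-fold and overlapped H3K4me2. The highest H3K4me2 peaks with no FLAG summit lay on chromosome 11, at 94901297 to 94903942 (8.74-fold, 546 tags) and 119088719 to 119090959 (10.98-fold, 386 tags).

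Peaks of the 3 FLAG lists were densest together on chromosome 13, in the 100-kb window from 23600001 to 23700000. It held 10 EGFP_OK, 9 Pax6, 9 Etv6 and 7 H3K4me2 peaks. Other dense windows held unequal numbers of peaks. A window on chromosome 4 (29000001 to 29100000) held 9 EGFP_OK peaks, 1 Pax6 peak and 1 Etv6 peak. A window on chromosome 18 (39000001 to 39100000) held 12 Etv6 and 7 Pax6 peaks and 0 EGFP_OK peaks. A window on chromosome 6 (114500001 to 114600000) held 18 H3K4me2 peaks, with 2 Etv6 peaks and no peak of the other FLAG lists.

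**Figure D4:**
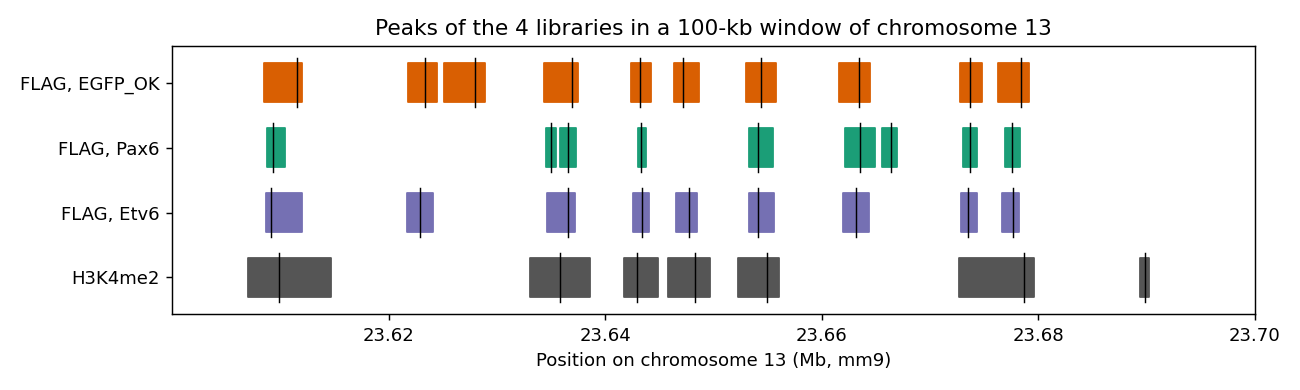
Peaks (coloured bars, to scale) and summits (black lines) of the 4 libraries along chromosome 13 (Mb, mm9, horizontal axis) from 23600001 to 23700000. The 10 EGFP_OK, 9 Pax6 and 9 Etv6 peaks fall largely at the same positions, most of them within H3K4me2 peaks.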

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

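The test in this part was chosen after the top regions had been seen. Peaks on chromosome Y and on unplaced sequences were outside the comparisons and were flagged because each list held more than 3 of them. That limit is a bound for a count of 0 and was not an expected number here, so passing it is no surprise by itself. There were 38 in the EGFP_OK list, 42 in Pax6, 53 in Etv6 and 111 in H3K4me2. In every library the highest was the same unplaced region, starting between 5495006 and 5495388, with 952, 647, 947 and 427 tags in that order.

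Among the first ranks, the same places recurred whatever the antibody, with 6 regions in the top 20 of all 4 lists, while 5 of the top-20 peaks of EGFP_OK were in no other FLAG list. Over the 6 regions the median ratio of Pax6 to Etv6 tags was 0.956, with a range of 0.735 to 1.02, against 0.290 over all matched peaks and 0.220 for the libraries' kept tags. A candidate explanation is that the limit of 1 tag per position caps the counts where reads pile up, but the near-equal counts of these regions prompted the idea and cannot also test it. Their tags made up 12.03% to 35.6% of the positions of both strands in EGFP_OK, 11.05% to 53.3% in Pax6, 17.2% to 40.9% in Etv6 and 14.5% to 43.95% in H3K4me2, so the peaks were not filled from end to end. Copy number and biological explanations were not tested. Leaving these and the other top-20 regions out took the Pax6 list from 16604 to 16561 peaks. So few were removed that the Pax6 and Etv6 overlap, 72.6% before and 72.5% after, could hardly move whatever these regions are.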

How the results depend on the processing

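Every alternative kept Pax6 with Etv6 as the pair with the largest share of Pax6 peaks, and kept the order Etv6, Pax6, EGFP_OK for summits in H3K4me2, but most shares moved by more than their counting interval. The share of Pax6 peaks with an Etv6 peak was 65.6% at a reciprocal overlap of 50%, 63.1% with summits within 250 bp, 80.4% at a score of at least 100 in both lists, 55.2% with equal list lengths and 71.1% without peaks wider than 3 kb. In that order, EGFP_OK peaks with an Etv6 peak gave 17.3%, 13.98%, 13.1%, 14.5% and 20.2%. Pax6 peaks with an EGFP_OK peak gave 15.6%, 13.5%, 15.9% and 13.7% under the first 4, and Pax6 peaks with both others gave 12.2%, 10.1%, 13.6%, 9.35% and 15.7%. Under the alternatives that used circular shifts, the fold lay between 24.7 and 97.8 for Pax6 with Etv6, between 6.56 and 21.7 for EGFP_OK with Etv6, and between 7.40 and 22.8 for Pax6 with EGFP_OK. The shares of the lists among the 83716 pooled regions of the 4 lists, used in place of shifts, gave 2.00 for Pax6 with Etv6 and 1.45 for Pax6 with both others. They turned the other 2 pairs below 1, to 0.604 for EGFP_OK with Etv6 and 0.634 for Pax6 with EGFP_OK. The pool holds only the regions of the lists themselves, so it sets a higher expected value by construction, and unrelated lists would also fall below 1. Summits in H3K4me2 were 29.8% for EGFP_OK, 46.9% for Pax6 and 55.0% for Etv6 when the whole peak counted, 30.96%, 48.0% and 55.9% within 1 kb, 24.9%, 47.7% and 57.8% at a score of at least 100, and 22.1%, 37.9% and 49.8% without peaks in all 3 FLAG lists. With equal list lengths they were 25.8% for EGFP_OK and 56.8% for Etv6. Ranking by fold enrichment in place of the score changed the difference between the highest and the lowest 10%, in percentage points, from 44.9 to 8.18 for Pax6 peaks with Etv6, from 71.3 to 44.9 for Etv6 peaks with Pax6, from 5.72 to -16.1 for EGFP_OK peaks with Etv6, from -3.17 to -29.1 for EGFP_OK in H3K4me2, from 8.52 to -14.9 for Pax6 in H3K4me2 and from 19.8 to -3.51 for Etv6 in H3K4me2. For these and the other changes the cause was not tested. A score of at least 100 left 12883 EGFP_OK, 4202 Pax6 and 14063 Etv6 peaks. Leaving out the top-20 regions, adding the unplaced sequences or leaving out chromosomes 3, 9 and 14, all chosen after seeing the data, moved no share beyond its interval. The top-20 regions and the unplaced sequences hold so few peaks that the shares could hardly move. Not run were the alternatives with a false discovery rate, for which the lists hold no column, and those of the promoter, gene list and motif results, which need an mm9 genome or annotation. No paired analysis was possible because each group holds 1 library. The Pax6 library's 5288154 kept tags limit what can be said of sites missing from its list.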

Other observations

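Of the tests in this part, that of carry-over by matched tags was set before its value was seen, and the others, carry-over by kept tags and by score included, were chosen after the overlaps had been seen. With 1 library per factor, each hypothesis below was found and tested on the same lists.

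Pax6 and Etv6 belong to different families of transcription factor, yet 72.6% of the Pax6 peaks had an Etv6 peak. Carry-over of a constant share of the Etv6 library into the Pax6 library, as large as the ratio of matched peaks, was predicted to leave under 5% of strong Etv6 peaks without a partner. Of the 2770 that reach at least 38 tags when scaled by that ratio, 19.6% (18.2 to 21.2) had none. When scaled by kept tags, 15.4% (13.5 to 17.4) had none. Without scaling, 8.60% (7.20 to 10.2) of the 1418 with a score of at least 300 had none. By kept tags, carry-over at a ratio of 0.220 would make up the whole Pax6 library, and at the matched ratio of 0.290 more than all of it. The scaled values argue against carry-over at those extreme ratios only. A smaller constant share predicts fewer tags and more peaks without a partner, so these values cannot exclude it. Background of the FLAG antibody as the source of most of the overlap would recur in the EGFP_OK library, but 22.9% (22.1 to 23.6) of the shared sites had an EGFP_OK peak. So did 38.5% (34.3 to 42.8) of Pax6 peaks with a score of at least 200 and 32.02% (29.6 to 34.5) of Etv6 peaks with a score of at least 300. The 22.9% could not have been a majority, since only 3342 of the 16604 Pax6 peaks had an EGFP_OK peak. It restates the overlap counts and is no separate test. The strongest shared sites went the other way. Of the 120 with a Pax6 score of at least 300, most, 64.2% (54.9 to 72.7), had an EGFP_OK peak. That is what background predicts, so it stays open there. Marking by H3K4me2 alone, if its list were complete, would leave chance overlap outside the H3K4me2 peaks, but there the overlap was 63.3%, against at most 3.40% under shifts. The 12050 Pax6 peaks with an Etv6 peak far outnumber the 7252 Pax6 summits inside H3K4me2. A high share outside was therefore certain from counts already seen and is no separate test. The H3K4me2 library is titled N31 and the Pax6 and Etv6 libraries NS. Marking under the calling limit, or present only in the cells titled NS, would give the same result and is not excluded. What stays open is background at any of the 2757 shared sites with an EGFP_OK peak, which may instead be binding of another tagged factor in that library. Also open, and not tested, are binding of both factors at the same sites and accessible chromatin that H3K4me2 does not mark. The same holds for H3K4me2 missed by its list and a background of the libraries titled NS that those titled N31 lack. It also holds for carry-over of a smaller share or at part of the sites.

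EGFP_OK peaks were the least often in H3K4me2, although the titles of these 2 libraries both name N31. Weak or chance peaks may be proposed, but at a score of at least 100 the share was 24.9% (24.1 to 25.6), no higher than the 26.9% of the whole list. The 10% with the highest folds had 18.5%, but ranking by fold gave lower shares at the top for Pax6 and Etv6 as well. That value is therefore not particular to EGFP_OK and decides nothing here. List length did not account for it either, since with 16604 top-ranked peaks from each list EGFP_OK had 25.8% (25.1 to 26.5) and Etv6 56.8%. The identity of the tagged protein, a change of the chromatin between the H3K4me2 library at 0 hr and the FLAG library, and repeats that gather reads without a control library stay open as untested explanations.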
